A study of Mus musculus with 4 samples.

How the data were processed

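RNA was measured in mouse P19 embryonal carcinoma cells, a line that turns towards neural fates when it is aggregated in retinoic acid. Per the labels, unmodified P19 cells were the control and P19 cells constitutively expressing human LIN28A, an RNA-binding protein that blocks maturation of the let-7 microRNAs, were the experimental cells. Both lines were aggregated for 4 days in 5e-07 M all-trans retinoic acid, and 2 arrays were made for each line. Per the labels' protocols, total RNA was turned into cDNA with an oligo(dT) primer and into biotin-labelled cRNA by in vitro transcription, which was hybridised to 1-colour Affymetrix arrays.

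The authors deposited 1 table of 22690 probe sets, whose values are linear intensity values with no log taken. The software that summarised probes into probe sets and scaled the arrays is not given in the sources used here. The mean after trimming 2% at each end was 150 in every array (lowest 150.1), so the deposited values were counted as scaled between arrays by the authors, under a rule set before the data were examined. The table holds no detection calls, so whether a low value lies above background could not be read from it. Every column of the table was used.

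Of the probe sets, 20393 carried exactly 1 gene symbol in the platform's annotation, 691 carried several, and 1555 probe sets other than controls had no entry there and are unnamed here. Of the gene identifiers, 20364 were found in a current mouse gene table, and 0 symbols needed an update. Probe sets with several symbols were tested but given no gene name. The 64 Affymetrix control probe sets were left out of all tests and used only as quality values.

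Values were turned into log2(value + 16). A difference on this scale understates the change of low genes. Probe sets whose mean log2 value over the 4 arrays lay under the 30th percentile (a linear value of about 8.04) were left out, which left 15838 probe sets and 8930 genes with 1 symbol. LIN28A was compared with control by limma 3.58.1 in R 4.3.3, with lmFit and eBayes, no trend and no block, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. With 2 arrays against 2, the smallest p that a two-sided exact permutation test of a single value can give is 0.333, so none is reported for single genes. The labels call the arrays repeats but do not say that they came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

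The 23 gene lists were fixed from general knowledge before the data were examined: pluripotency, neural progenitor, proneural and neurogenic transcription factors, neuronal, glial, retinoic acid response, Hox genes, let-7 targets, IGF axis, imprinted genes, cell cycle, ribosomal proteins, replication-dependent histones, mesoderm, endoderm, fibroblast and smooth muscle, neural crest, Notch pathway, Wnt pathway, BMP and TGF-beta pathway, Hedgehog pathway, hypoxia and glycolysis, and p53 and cell stress. Each gene was represented by its tested probe set with the highest mean. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera's estimated correlation and limma's fry run beside it. The estimated correlation rests on 2 residual degrees of freedom, or 1 with the replicate block, so a call lost under it decides little. A member was called higher or lower in both arrays when both LIN28A arrays lay on the same side of both control arrays.

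The genes named were also chosen by a rule set before the data were examined. It took Lin28a and Lin28b first, then the 10 genes with the largest rise and the 10 with the largest fall past the threshold. For genes past the threshold, both LIN28A arrays also had to lie on the same side of both control arrays. Where fewer passed, the genes with the smallest unadjusted p filled the places, without that condition. It further took up to 4 members of each list with the smallest p, and always Igf2, Hmga2, Igf2bp1, Neurog1, Neurod1, Dcx, Gfap, Sox2 and Pou5f1. Lin28b had no probe set that the annotation names, and was not analysed here. An item that the rule also covers is not reported here.

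The per-probe-set test was tested on simulated data, with 200 of 15838 probe sets changed in 10 simulations. With the differences between replicate numbers that the arrays show, it recovered 0% of probe sets changed 8-fold. With the replicate number as a block, the test recovered 97.0% of those changed 4-fold and 99.5% of those changed 8-fold in the same data, and 155 of its 1558 calls were false. Without those differences the test with no block recovered 92.8% of those changed 4-fold and 98.9% of those changed 8-fold. The simulated number difference was the same in both lines, and the 200 planted changes eased the adjusted threshold. These recovery rates therefore need not hold for the real arrays, where the block fit called 1 probe set. There Nnat, with a log2 difference of -2.63, had a block-fit adjusted p of 0.25, and Cacna2d3, with -2.11, had 0.16. In 20 simulations of independent genes over 8930 genes, camera recovered a shifted cell cycle list 20 times and called 1 of 440 other lists. These simulated arrays had no differences between replicate numbers, so that rate need not hold for the real arrays.

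Alternatives fixed in advance were a pseudocount of 1 or 64, no filter or a filter at the 50th percentile, quantile normalization, median centring, eBayes with trend or robust, the replicate number as a block, leaving out each array, other thresholds, 1 probe set per gene, averaged probe sets and an estimated correlation. Fits that left out 1 array had no block, so replicate numbers were unequal between the groups and differences between numbers entered the contrast. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.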

Results

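Gene expression was measured on 4 arrays of P19 cells after 4 days of aggregation in 5e-07 M retinoic acid, 2 of control cells and 2 of cells expressing human LIN28A. The arrays had median intensities of 35.8 and 38.6 in control and 29.0 and 36.7 in LIN28A cells, and 35.8% to 42.3% of their probe sets lay under an intensity of 16. The comparison asks which transcripts of differentiating P19 cells differ when LIN28A is kept on.

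The arrays differed more by replicate number than by cell line. Across probe sets, Pearson's r was 0.97 between control and LIN28A arrays of number 1 and 0.97 between those of number 2, against 0.93 between the control arrays and 0.94 between the LIN28A arrays; probe sets are not independent replicates. The first principal component held 63.6% of the variance and separated the numbers, and the second held 21.6% and separated the cell lines. Quality values moved with the number too. The 18S ribosomal RNA probe set read 677 in control 1 and 136 in LIN28A 1, against 9.20 and 11.3 in control 2 and LIN28A 2. The spike-in BioB read 524 and 269 in number 1 against 165 and 161 in number 2, and the B1 repeat probe set read 4520 and 5454.5 against 696 and 1012. The ratio of 3' to 5' signal was 4.71, 2.76, 3.37 and 3.09 for beta-actin and 1.15, 0.775, 1.12 and 0.821 for Gapdh in control 1, control 2, LIN28A 1 and LIN28A 2.

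**Figure D1:**
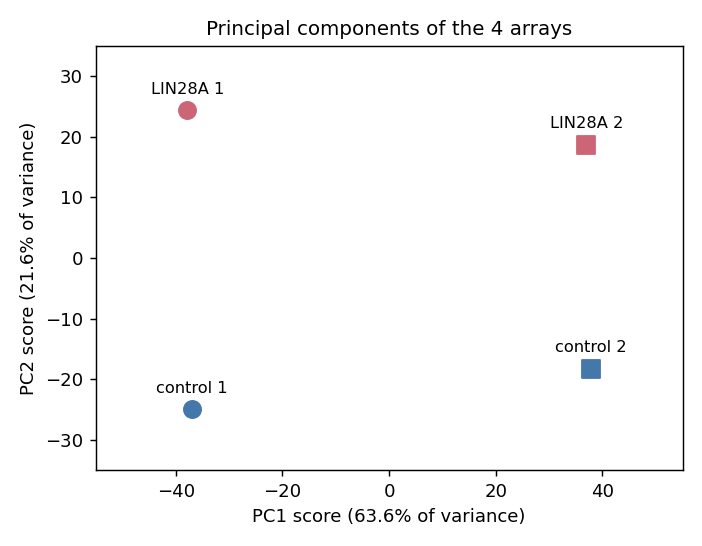
Scores of the 4 arrays on the first 2 principal components of log2 intensity, with circles for replicate number 1, squares for number 2, blue for control and red for LIN28A. The numbers lie apart on the first component (63.6% of variance) and the cell lines on the second (21.6%).

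The endogenous mouse Lin28a, which the arrays' probe sets measure and which does not check the human transgene, read 53.5 ± 32.2 (SD, n = 2) in control and 46.8 ± 13.2 (SD, n = 2) in LIN28A cells at the brighter probe set, with a log2 difference of -0.08 that becomes 0.06 under quantile normalization and 0.05 under median centring. Its second probe set read 22.2 ± 9.40 in control and 7.80 ± 1.13 in LIN28A cells (SD, n = 2). Neither passed the threshold.

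The genes with the smallest unadjusted p in each direction included imprinted and neuronal genes, although none passed the threshold over all probe sets in the fit without a block. Sall4, a zinc finger transcription factor of pluripotent cells, read 9.25 ± 10.1 in control and 139 ± 78.6 in LIN28A cells (SD, n = 2; log2 difference 2.58 ± 0.49 SE). Zcchc3, a zinc finger protein, read 7.05 ± 9.55 and 122 ± 65.1 (2.57 ± 0.47 SE), and its other probe set differed by 2.51. Peg3, a paternally expressed imprinted gene, read 0.650 ± 0.495 and 43.7 ± 6.22 at its leading probe set (1.84 ± 0.28 SE), and its brightest probe set read 36.3 and 3.20 in the control arrays against 635.7 and 181 in the LIN28A arrays. Meg3, a maternally expressed long noncoding RNA, read 24.4 ± 2.55 and 176 ± 127 (2.07 ± 0.51 SE, and 1.34 without LIN28A replicate 1). The malic enzyme Me1 differed by 1.68, the tetraspanin Tspan6 by 1.53 and the serine protease Htra1 by 1.39 (0.54 at its other probe set). The kinetochore gene Spc25 differed by 1.04 (0.23 at its other probe set) and the MAP kinase phosphatase Dusp9 by 1.04. Malat1 differed by 2.0 at its leading probe set, but its other probe sets differed by 0.64, 0.57, -0.08 and -0.33.

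On the other side, Nnat, the imprinted neuronatin gene, read 211 ± 120 in control and 18.1 ± 4.60 in LIN28A cells (SD, n = 2; log2 difference -2.63 ± 0.44 SE). The neuronal splicing factor Rbfox1 read 163 ± 54.9 and 28.2 ± 2.55, and Mapt, which encodes the microtubule protein tau, read 207 ± 35.1 and 48.8 ± 17.3. Mapt differed by -1.80 there, and by -1.19 and -0.35 at its other probe sets, where the arrays of the lines overlapped. The calcium channel subunit gene Cacna2d3 read 148 ± 51.8 and 21.2 ± 6.72, and the neuronal vesicle gene Nsg2 read 237 ± 57.0 and 51.9 ± 23.1. Vldlr, a reelin receptor gene, differed by -1.73, and all of its 4 probe sets lay below 0. The synuclein gene Sncg differed by -1.86, the protease gene Ctsc by -1.86, Mmd2 by -1.47 and the lysosomal gene Gusb by -1.43.

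**Figure D2:**
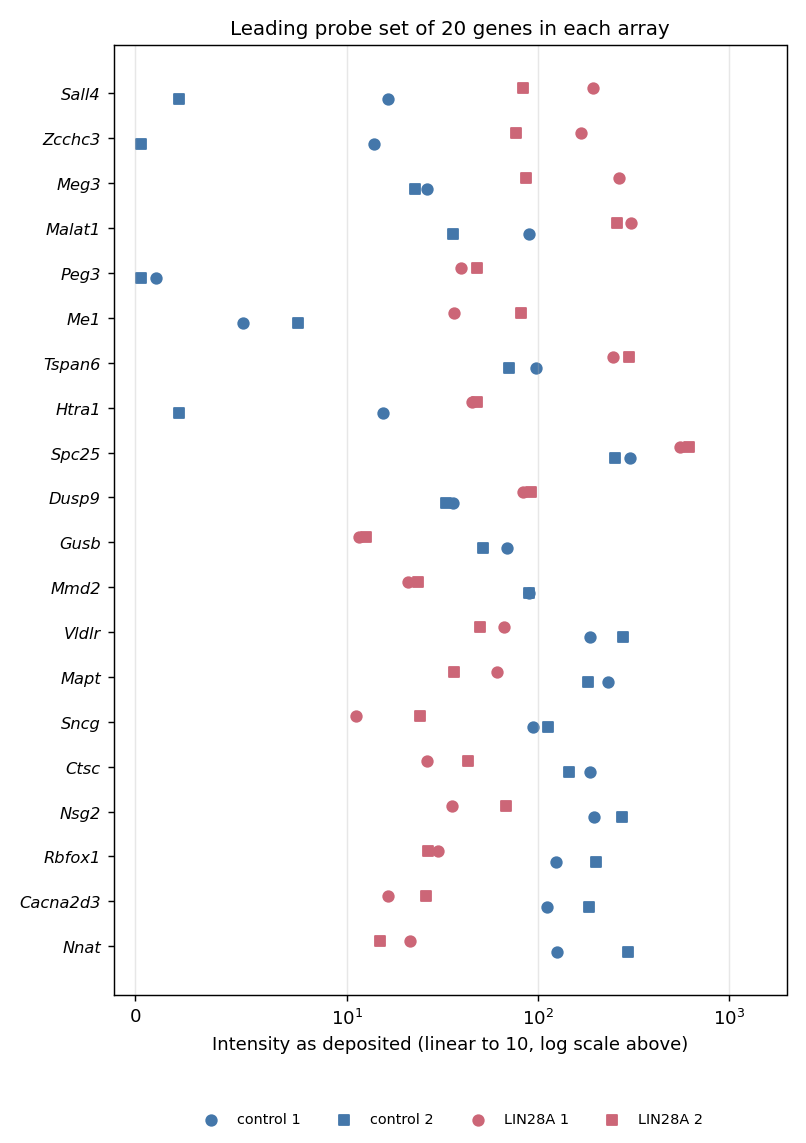
Deposited intensity (linear up to 10 and on a log scale above) of the leading probe set of each of 20 genes, with circles for replicate number 1, squares for number 2, blue for control and red for LIN28A. Both LIN28A arrays lie to one side of both control arrays for every gene shown, which a choice by smallest p favours, and no gene passed the threshold.

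Of 15838 probe sets, limma's test without a block called 0 higher and 0 lower at an adjusted p under 0.05. In simulations with the observed differences between numbers this test recovered 0% of 8-fold changes, so it could call next to nothing. At an unadjusted p under 0.05 there were 70 higher and 192 lower. The 792 expected by chance alone assumes independent arrays, and same-numbered arrays deviated together. That widened the spread in this fit, so a count under 792 does not mean less change than chance. With the replicate number as a block there were 468 higher and 890 lower. Without the block, the split became 124 higher and 167 lower under quantile normalization and 167 higher and 107 lower under median centring. Median centring moved the median difference over all probe sets from -0.05 to 0.08 (log2). Both LIN28A arrays lay above both control arrays for 10.03% of probe sets and below for 15.5%. For independent arrays, 16.7% would do so by chance in each direction. The differences between lines of number 1 and of number 2 correlated with r = 0.17 across probe sets.

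Of the genes followed whatever their p, none passed the threshold. Igf2 read 169 and 94.1 in the control arrays and 139 and 1489 in the LIN28A arrays, so its difference rested on LIN28A 2 (log2 difference -0.26 in number 1 and 3.77 in number 2). Pou5f1, the Oct4 gene, read 30.3 and 374 in control and 28.7 and 775 in LIN28A cells. Hmga2, a let-7 target, differed by 0.81 in number 1 and -0.07 in number 2, and Igf2bp1 by 1.08 and 0.09, or by 1.22 and 0.61 at its other probe set. Sox2 read 1800 ± 145 and 1426 ± 186 (SD, n = 2), Neurog1 read 557 ± 2.69 and 514 ± 29.1 (a log2 difference of -0.11 that was 0.012 under median centring), and Dcx differed by -0.40, with -1.09 to 0.30 without 1 array. Neurod1 differed by -0.22 at its brighter probe set and by 0.09 at the other. The glial gene Gfap read 15.7 ± 9.05 and 6.40 ± 7.21, both under the pseudocount.

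Cell division genes lay higher in LIN28A cells and neuronal genes lower. Of 37 measured cell cycle genes, 35 lay above 0 and 24 were higher in both arrays, with a median log2 difference of 0.47 (camera adjusted p = 6.8e-15), and 0.38 within number 1 and 0.55 within number 2. That call was lost with an estimated correlation (adjusted p = 0.85), and the median was 0.28 without control replicate 2. Mki67, the Ki-67 gene, read 680 ± 142 in control and 1190 ± 70.1 in LIN28A cells (SD, n = 2). The mitotic kinase gene Plk1 read 206 ± 6.43 and 354 ± 43.5, and the replication genes Cdc45 and Rrm1 differed by 0.61 and 0.69 (Rrm1 0.45 without control replicate 2). Of 36 neuronal genes, 34 lay below 0 and 9 were lower in both arrays, with a median of -0.46 (camera adjusted p = 1.2e-07), and -0.60 within number 1 and -0.33 within number 2. That call too was lost with an estimated correlation (adjusted p = 0.85), and fry's directional test did not make it (adjusted p = 0.85). Over all probe sets, 10.03% were higher in both arrays and 15.5% lower. Besides Mapt, the RNA-binding protein gene Elavl4 read 342 ± 156 and 160 ± 42.4 (log2 difference -0.98, and -0.52 without control replicate 2), the vesicular GABA transporter gene Slc32a1 read 18.2 ± 3.54 and 2.80 ± 1.56, and the homeobox gene Lhx5 read 43.0 ± 14.4 and 15.5 ± 1.48. No member of either list passed alone, whether adjusted over all probe sets (0) or adjusted over the list alone (0). The neuronal median was -0.043 without LIN28A replicate 1, -0.24 without control replicate 2, -0.76 without control replicate 1 and -0.81 without LIN28A replicate 2. Those fits had no block and unequal replicate numbers between the lines. Part of the difference between numbers, a median of 0.65 for neuronal genes, therefore entered them.

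A further 4 lists passed camera. Each was lost with an estimated correlation (adjusted p = 0.85), and fry's directional test called none of them (adjusted p = 0.85 for each). Over all probe sets, 10.03% were higher in both arrays and 15.5% lower. Of 32 let-7 targets, 24 lay above 0 and 11 were higher in both arrays, with a median of 0.28 (adjusted p = 0.0018; 0.28 in number 1 and 0.11 in number 2). Among them the cyclin gene Ccnd1 read 212 ± 52.8 and 426 ± 78.2 (SD, n = 2) and the ribonucleotide reductase gene Rrm2, also a cell cycle list gene, read 1300 ± 299.5 and 2028 ± 220. Rrm2 differed by 0.65, and by 0.42 without control replicate 2. Without control replicate 1 the let-7 median was 0.10 and not called (adjusted p = 0.064), and without LIN28A replicate 2 it was 0.035. It was 0.14 with the probe sets of a gene averaged and 0.18 with no filter. Of 24 hypoxia and glycolysis genes, 23 lay below 0, with a median of -0.52 (adjusted p = 2.6e-05), but it was -0.99 in number 1 and -0.03 in number 2. It was 0.26 without control replicate 1 and -0.16 without LIN28A replicate 2, not called in either case, and -1.20 without control replicate 2 and -0.84 without LIN28A replicate 1. Vegfa, the vascular growth factor gene, read 135 ± 23.8 and 45.1 ± 5.59, the phosphofructokinase gene Pfkp read 117 ± 7.64 and 36.3 ± 6.29, and Ero1a and Ndrg1 differed by -1.05 and -1.36, with Ndrg1 at -0.66 without control replicate 1 and -2.05 without control replicate 2. Of 45 ribosomal protein genes, 41 lay below 0, with a median of -0.38 (adjusted p = 0.00015; -0.48 and -0.29 in numbers 1 and 2), which was -0.03 and not called under quantile normalization (adjusted p = 0.55), and 0.022 without control replicate 1 and -0.062 without LIN28A replicate 2, not called in either case. It was -0.78 without control replicate 2, -0.70 without LIN28A replicate 1 and -0.25 under median centring. Of the 45 ribosomal protein genes, only 3 were lower in both arrays and 1 was higher. Of the 24 hypoxia and glycolysis genes, 4 were lower in both arrays and 0 higher. Control 1, without which the hypoxia and ribosomal medians lay above 0, was also the array with the highest 18S (677), BioB (524) and beta-actin 3' to 5' (4.71) values. In these lists number 2 minus number 1 had medians of -0.81 and -0.74, and leaving out 1 array let part of that enter. An effect of control 1 itself cannot be told apart from it. The number 2 medians, which do not use control 1, were -0.03 and -0.29. Of 22 fibroblast and smooth muscle genes, 15 lay above 0, with a median of 0.12 (adjusted p = 0.012) that was -0.17 in number 1 and 0.56 in number 2, and -0.020 without control replicate 2 and -0.040 without LIN28A replicate 2. It was 0.39 without control replicate 1 and 0.34 without LIN28A replicate 1. Other settings moved it to between 0.058 (pseudocount 64) and 0.29 (filter at the 50th percentile). Of this list's genes, 6 were higher in both arrays and 1 was lower. Its Col3a1 differed by 1.52 (0.42 in number 1 and 2.61 in number 2, and 0.89 without control replicate 2), Acta2 by 0.91 (0.57 without control replicate 2) and Lox by -1.0.

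**Figure D3:**
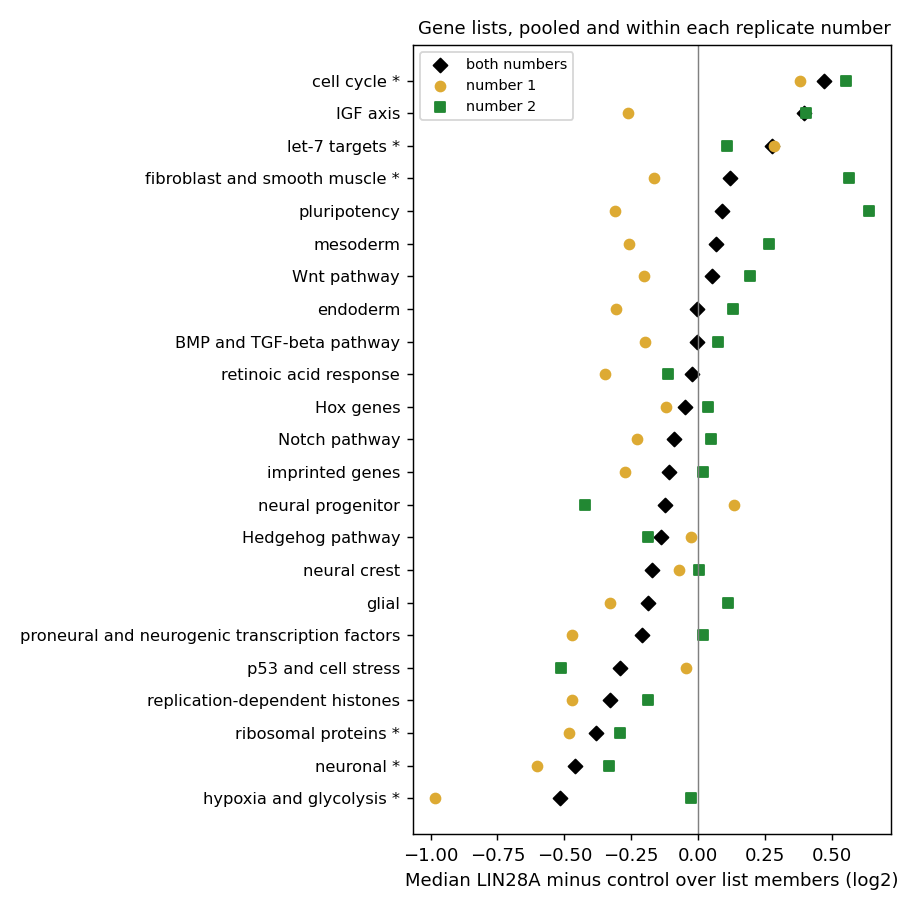
Median log2 difference of LIN28A minus control over the measured members of each of 23 gene lists, pooled (black diamonds), within number 1 (yellow circles) and within number 2 (green squares), with an asterisk for a camera adjusted p under 0.05. Cell cycle (0.38 and 0.55) and neuronal genes (-0.60 and -0.33) kept their side in both numbers, while hypoxia and glycolysis genes lay at -0.99 and -0.03.

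Pluripotency genes had a median of 0.09 (camera adjusted p = 0.083, and 0.042 with the replicate block) that was -0.31 in number 1 and 0.64 in number 2. Without 1 array it was 0.60 (LIN28A replicate 1), 0.26 (control replicate 1), -0.048 (control replicate 2) and -0.37 (LIN28A replicate 2). Sall4 passed when adjusted over the list alone (adjusted p = 0.038), and Dnmt3b read 113 ± 32.2 and 193 ± 39.2 (SD, n = 2). Dnmt3b differed by 0.70, and by 0.45 without control replicate 1. Imprinted genes had a median of -0.11 (adjusted p = 0.71; 0.020 under median centring), with Nnat and Peg3 the 2 genes to pass when adjusted over the list alone, and Slc38a4 differed by -1.61 (-0.80 without LIN28A replicate 2 and -2.41 without LIN28A replicate 1). The IGF axis (median 0.40, with -0.26 in number 1 and 0.41 in number 2), the proneural and neurogenic transcription factors (-0.21, with -0.47 and 0.02) and the p53 and cell stress genes (-0.29, with -0.04 and -0.51) each had an adjusted p of 0.083. With the replicate block, camera gave the IGF axis an adjusted p of 0.038. Leaving out 1 array turned the sign of each of these lists. The median was -0.046 for the IGF axis without LIN28A replicate 2 and -0.0095 without control replicate 2. It was 0.013 for the proneural list without LIN28A replicate 1 and 0.073 for the stress list without control replicate 2. The other fits kept the sign, at 0.32 and 0.20 for the IGF axis without control replicate 1 and LIN28A replicate 1. They gave -0.71 to -0.11 for the proneural list and -0.62 to -0.26 for the stress list. Within them, Nhlh1 and Neurog2 differed by -0.73 and -0.46 (-0.39 and -0.17 without LIN28A replicate 1), and the stress genes Hspa1b and Ddit4 by -1.41 and -1.47. Ddit4 differed by -0.79 in number 1 and -2.15 in number 2, and by -0.57 without control replicate 2 and -2.37 without control replicate 1.

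Camera's calls at a preset correlation were also run on the other ways to split the 4 arrays. The crossed split set control 1 with LIN28A 2 against the other arrays, following neither cell line nor number. It called 13 of the 23 lists, against 6 for the cell lines. Hypoxia and glycolysis and fibroblast and smooth muscle were called in both. Cell cycle (0.15), neuronal (0.11), let-7 target (0.016) and ribosomal protein genes (0.095) were not called in the crossed split. Its lowest camera adjusted p, 1.6e-07 for neural progenitor genes, was near the 1.2e-07 of the neuronal list between the cell lines. Camera's adjusted p-values at the preset correlation therefore cannot be read at face value on these arrays. The split by number called 5 lists, with medians of -0.26 for cell cycle, 0.65 for neuronal and -0.74 for ribosomal protein genes.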

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

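The replicate block with quantile normalization, with eBayes trend or with an estimated correlation was chosen after seeing the data; the other settings were planned, and where a value moved the cause was not tested. The count of probe sets called was 0 in each direction under every planned setting except the replicate block. Same-numbered arrays deviated together (r = 0.62 across probe sets), but the arrays share only a number in the labels. The replicate block called 1 probe set higher (Peg3, adjusted p = 0.028) and 0 lower, with 468 higher and 890 lower at an unadjusted p under 0.05 and 5 lists higher, adding pluripotency and the IGF axis. With quantile normalization as well it called 3 higher, with 700 and 707 at an unadjusted p under 0.05, and 6 lists higher; with eBayes trend it called 3, with 599 and 956. Without the block, probe sets higher at an unadjusted p under 0.05 numbered 167 with median centring, 158 with no filter, 145 with pseudocount 64 and 124 with quantile normalization, and 80 to 133 without 1 array. Those lower numbered 107 with median centring, 362 with no filter, 305 with pseudocount 1 and 89 with the filter at the 50th percentile, and 148 to 317 without 1 array. An estimated correlation, without or with the replicate block, called 0 lists (adjusted p 0.85 and 0.97) at the same medians: cell cycle 0.47, let-7 targets 0.28, fibroblast and smooth muscle 0.12, neuronal -0.46, hypoxia and glycolysis -0.52 and ribosomal proteins -0.38. Quantile normalization called 5 lists higher and took ribosomal proteins to -0.027, without or with the replicate block (adjusted p 0.55 and 0.58). Median centring and the filter at the 50th percentile each called 5 lists lower. Without 1 array, 2 to 5 lists were higher, and medians ranged from -0.040 to 0.39 for fibroblast and smooth muscle, -1.20 to 0.26 for hypoxia and glycolysis, 0.035 to 0.30 for let-7 targets, -0.81 to -0.043 for neuronal and -0.78 to 0.022 for ribosomal proteins; cell cycle ranged from 0.28 to 0.66 and was called in each. Uncalled lists also changed sign without 1 array: BMP and TGF-beta -0.29 to 0.13, Hox -0.16 to 0.15, IGF axis -0.046 to 0.32, Notch -0.22 to 0.17, Wnt -0.12 to 0.16, endoderm -0.16 to 0.21, glial -0.36 to 0.059, mesoderm -0.17 to 0.17, neural progenitor -0.32 to 0.098, p53 and cell stress -0.62 to 0.073, pluripotency -0.37 to 0.60 and proneural -0.71 to 0.013. Genes did so too: Dcx -1.09 to 0.30, Hmga2 -0.28 to 1.02, Igf2bp1 -0.73 to 1.91, Lin28a -0.57 to 0.41, Neurod1 -1.30 to 0.85 and Pou5f1 -1.59 to 2.56. Median centring turned BMP and TGF-beta to 0.12, Hox to 0.080, Notch to 0.038, endoderm to 0.13, imprinted genes to 0.020, neural progenitor to 0.0050, retinoic acid response to 0.10, Lin28a to 0.048 and Neurog1 to 0.012. Quantile normalization, with or without the replicate block, turned BMP and TGF-beta to 0.061, endoderm to 0.091 and Lin28a to 0.062. The filter at the 50th percentile turned BMP and TGF-beta to 0.043, Hedgehog to 0.15 and endoderm to 0.14. Averaged probe sets turned BMP and TGF-beta to 0.043 and pluripotency to -0.030, no filter turned mesoderm to -0.025 and pluripotency to -0.036, pseudocount 1 turned pluripotency to -0.022, and pseudocount 64 turned BMP and TGF-beta to 0.013 and endoderm to 0.024. Of 936 values of the named genes under alternatives, 921 kept their sign, but 28 of 63 named probe sets moved over 1.5 times or turned without 1 array. The fits without 1 array had no block, so all such moves also hold part of the difference between the numbers. Low signal limits what the arrays can show, as 35.8% to 42.3% of probe sets lay under the pseudocount.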

Other observations

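The gene list tests and the normalizations used in this part were planned, and the tests by the ratio of probe set correlations and the count of second-brightest probe sets were set before their results were seen, whereas the contrast of the numbers, the same ratio for the cell lines, the splits, the other probe sets of leading genes, the size of imprinted changes, and the use of within-number, quantile and neural progenitor medians as tests of an explanation were chosen afterwards. Among signalling and patterning genes, none of which passed the threshold over all probe sets, Hes5, a Notch effector of neural progenitors, read 190 ± 6.15 in control and 631 ± 415 in LIN28A cells (SD, n = 2), with differences of 2.22 in number 1 and 0.75 in number 2. The neural progenitor list had a median of -0.12 (camera adjusted p = 0.62) and the Notch pathway -0.09 (adjusted p = 0.86, with camera's direction and the median on opposite sides). The Hox gene list had a median of -0.05 (adjusted p = 0.71), and its Hoxd1 read 76.4 ± 6.72 and 26.3 ± 5.30 (SD, n = 2). The neural crest list had a median of -0.17 (adjusted p = 0.68), and its endothelin receptor gene Ednrb read 61.9 ± 15.5 and 25.7 ± 4.31. The Hedgehog list had a median of -0.14 (adjusted p = 0.71), with Gas1 differing by -0.66 (-0.38 without LIN28A replicate 2), and the Wnt list 0.05 (adjusted p = 0.59), with Wnt4 differing by -0.94 (-0.35 without LIN28A replicate 2 and -1.54 without LIN28A replicate 1). Under median centring the neural progenitor, Notch and Hox medians lay above 0, at 0.0050, 0.038 and 0.080. The filter at the 50th percentile took the Hedgehog median to 0.15, and the Wnt median ran from -0.12 to 0.16 without 1 array.

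Among other cell types, the glial list had a median of -0.19 (adjusted p = 0.56), mesoderm 0.07 (adjusted p = 0.71) and endoderm -0.0020 (adjusted p = 0.64), where Lamb1, a basement membrane laminin gene, read 64.7 ± 27.0 in control and 190 ± 117 in LIN28A cells (SD, n = 2). Lamb1 differed by 0.30 in number 1 and 2.23 in number 2, and by 0.65 without LIN28A replicate 2. The BMP and TGF-beta list had a median of -0.0032 (adjusted p = 0.64), with camera's direction up for it and for endoderm, against the sign of the median. The retinoic acid response list had a median of -0.02 (adjusted p = 0.71), and median centring took it to 0.10, endoderm to 0.13 and BMP and TGF-beta to 0.12. The 6 replication-dependent histone genes had a median of -0.33 (camera adjusted p = 0.27), with -0.088 without control replicate 1 and -0.57 without control replicate 2, and changed in either direction by fry's mixed test (adjusted p = 0.020), with the linker histone gene H1f2 at 241 ± 46.2 and 114 ± 7.42 (SD, n = 2). No list passed fry's directional test (lowest adjusted p 0.85).

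Between the replicate numbers, with the cell line as a term, limma called 926 probe sets higher and 405 lower in number 2. As number 2 minus number 1, the neuronal list had a median of 0.65 (camera adjusted p = 2.8e-07) and the proneural list 0.43 (adjusted p = 0.011). Ribosomal protein genes had -0.74 (adjusted p = 1.8e-16), hypoxia and glycolysis genes -0.81 (adjusted p = 3.0e-08) and cell cycle genes -0.26 (adjusted p = 0.0026). Each call was lost with an estimated correlation (adjusted p = 0.97). That estimate rested on 1 residual degree of freedom and gave all 23 lists the same adjusted p, so the loss decides little. A candidate explanation is labelling, hybridisation or probe effects. Across 3606 genes with at least 2 tested probe sets, the number difference correlated at r = 0.64 for the same probe set in both lines. For another probe set of the gene it was 0.21, a ratio of 0.32 (95% bootstrap interval 0.28 to 0.37), under the limit of 0.5 set for such effects. The same ratio for the cell line difference was 0.92, but from weak correlations of 0.19 and 0.17, and no interval was computed for it. A later neural stage of the number 2 cultures stays open. Of 15 neuronal genes, 11 had a second-brightest probe set higher in number 2 in both lines, and 2 had it lower in both. A one-sided exact binomial test against a share of 0.5 gave p = 0.059. That share is not the one expected by chance for a probe set higher in both of 2 lines that deviated together. No share over all second-brightest probe sets was computed, so this count decides nothing. The pluripotency genes Pou5f1 (3.61), Nr0b1 (1.87) and Gdf3 (1.24), picked after their values were seen, were also higher in number 2. Sall4 was lower (-0.96), and the pluripotency list had a median of -0.06 (camera adjusted p = 0.86).

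For the higher cell cycle and lower neuronal genes in LIN28A cells, the tables argue against brightness-dependent scaling as the whole cause. Quantile normalization left medians of 0.46 and -0.43. The within-number medians cannot test the number difference, since each number held 1 array of each line and a shared shift cancels. The smallest of these 4 medians was 0.33 in size, on the same side in both numbers, each from 1 array against 1. Whether chance sorting of arrays gives as much cannot be decided, since the 4 arrays have only 3 splits; 1 of them, the real one, reached a cell cycle median of 0.47, and the largest other reached 0.26, while for neuronal genes the split by number reached 0.65 against -0.46 for the real one. Fewer neurons and more dividing progenitors may lie behind both, but the neural progenitor list, at -0.12 with an adjusted p of 0.62, does not decide it. Each group is a single cell line, so an effect of LIN28A and any other difference between the lines cannot be told apart.

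For Peg3, Meg3, Sall4 and Zcchc3, higher, and Nnat, lower, in LIN28A cells, cross-hybridisation of single probe sets stays open, since Nnat has no other probe set and the other 4 genes are too few for a test. The other probe sets of 4 of these 4 genes went the way of the leading one (one-sided exact binomial p by gene 0.0625, the smallest possible), at 2.17 and 3.50 for Peg3, 2.51 for Zcchc3, 0.62 for Sall4 and 0.29 to 1.72 for Meg3, all read on the same 4 arrays. Whether imprinted genes differ as a class between the lines stays open. Their median size of change, 0.34, lay at percentile 98.3 of 10000 matched random lists, but fry's mixed test gave an adjusted p of 0.57. A clonal difference in imprinting could not be tested with 1 line per group.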
